A study of Mus musculus with 8 samples.

How the data were processed

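Total RNA from the myocardium of 8 Pcyt2+/- mice, 4 male and 4 female, was measured on Affymetrix arrays, 1 array per mouse. Per the labels, the mice were 8 months old, hearts were collected 3 to 4 h after lights on and snap-frozen, and biotinylated cRNA was made from 100 ng of total RNA. The deposited values are log2 expression values per probe set, summarised and normalized between arrays with RMA, per the submitters' processing notes; the version of RMA is not given in the sources used here. The log2 scale was checked on the deposited values, whose array medians lay between 3.88 and 3.91 for all 41345 probe sets. A deposited workbook gave positions and probe numbers for 34351 of these probe sets. Its 8 columns of values carry names that match no sample label and were not used.

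Probe sets were given a gene from the platform table where it names 1 symbol (23521 probe sets) and otherwise from the workbook where that names 1 symbol (6383). Probe sets with several symbols (3190) or none (8251) were left out of the gene tests. Older symbols were replaced by current ones. For the 1311 genes with more than 1 probe set, the probe set with the highest mean over the 8 arrays was taken, which left 28273 genes, 26972 of them autosomal. Positions are those of the workbook, whose genome build is not given in the sources used here. Of 23738 transcript clusters matched by gene, 94.0% start within 5000 bases of the gene in GRCm38.

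Groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. Males and females were compared with limma 3.58.1 (lmFit and eBayes with no trend) in R 4.3.3, with no further normalization and no filter on dim genes. Differences are male minus female on the log2 scale, tests are two-sided, and p was adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. For autosomal genes p was adjusted again over autosomes alone. Standard errors are limma's moderated ones, with 3.94 prior degrees of freedom. Pcyt2 and list means were also compared by an exact permutation test of 4 against 4 values. The replicate numbers of the labels were not used as pairs.

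The 33 gene lists covered sex-chromosome genes, lipid and energy metabolism, contraction, stress responses, hormone signalling and markers of cell types. Each was tested with limma's camera, which sets a list against all other genes, at a preset correlation of 0.01, and p was adjusted over the 33 lists. Camera with an estimated correlation and limma's fry were run beside it. Within each list, p of the members was adjusted over the list alone as well as over all genes. A list mean is the mean, per array, of the members' deviations from their means over the 8 arrays.

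Genes were named by a fixed rule: Pcyt2; Xist, Ddx3y, Eif2s3y, Kdm5d and Uty as a check of the labels; autosomal genes past the threshold, or the 5 with the smallest p in a direction where fewer pass; X-linked genes past the threshold; and up to 4 members of each list, those past the threshold first and then those with the smallest p. The rule took 140 genes, not all of which are printed, and some are not reported here. Gene models without a proper name were counted and not named. Ano5 is named because it passed over all genes, though not over autosomes alone.

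Alternatives covered normalization between arrays, filters on dim genes, eBayes with a trend, array weights, the replicate number as a block, each array left out in turn, other ways to reduce probe sets to genes, other thresholds and other list tests. A comparison with the workbook's own values was planned and not run, because its columns could not be matched to samples. Covariates for atrial and adipocyte markers and a shortened adipocyte list were chosen after seeing the data. Terms of the platform annotation, also chosen after seeing the data, were tested with camera over autosomal and other genes outside X and Y. The procedure was tested on simulated data with 200 changed genes among 28273, in 10 simulations. It recovered 48.2% of changes of 0.5 on the log2 scale and 96.7% of changes of 1, with 5.3% of calls on unchanged genes. These shares hold for 200 changed genes with independent noise. Where fewer genes change, the adjustment is stricter and recovery lower, so the shares do not give the power of the real comparison. In the real data C7, with a difference of 1.60, did not pass (limma adjusted p = 0.280). Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.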

Results

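Gene expression was measured in the myocardium of 8 mice heterozygous for Pcyt2 (Pcyt2+/-), 4 males and 4 females, with 1 microarray per mouse. Pcyt2 encodes CTP:phosphoethanolamine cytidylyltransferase, the enzyme that makes CDP-ethanolamine on the way to phosphatidylethanolamine, a main phospholipid of cell membranes. The mice were 8 months old and the hearts were taken 3 to 4 h after lights on. The labels call the arrays of each sex biological replicates 1 to 4; whether any mice shared a litter or a day of processing is not given in the sources used here. Wild-type hearts are not analysed here, so each comparison is between the sexes of heterozygous mice, and nothing measured here shows what the loss of a copy of Pcyt2 does. Each array gave a log2 expression value for 41345 probe sets, with array medians between 3.88 and 3.91. After naming, 28273 genes could be compared, of which 26972 lie on autosomes, 1206 on X and 28 on Y. Pairs of arrays correlated at 0.989 to 0.991 across genes, which are not independent replicates, and no pair shared more than 16 identical values, so all 8 arrays were counted as separate samples. Their number limits the precision of every value.

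The heterozygous gene itself and the pathway it belongs to did not differ measurably between the sexes. Pcyt2 (chromosome 11, 120610087 to 120617936, 23 probes) was at 5.55 ± 0.27 (SD, n = 4) on the log2 scale in males and 5.47 ± 0.19 (SD, n = 4) in females. The log2 difference, male minus female throughout, was 0.08 with a standard error of 0.14 and a 95% confidence interval from -0.24 to 0.39 (adjusted p = 0.960). The unadjusted limma p was 0.599 and the exact two-sided permutation test gave p = 0.743, where 0.0286 is the smallest p that 4 arrays against 4 allow. Of 16 measured genes of phosphatidylethanolamine and phosphatidylcholine synthesis, 0 passed an adjusted p of 0.05 over all genes and 0 when p was adjusted over the list alone, while 2 had an unadjusted limma p under 0.05. The members with the smallest p were choline kinase Chka (log2 difference -0.29) and the phosphatidate phosphatase Lpin3 (-0.33), both with an adjusted p of 0.850. A dimmer probe set of Chka gave 0.25, the opposite direction. The list as a group had a median difference of 0.01 and a mean of -0.02 (camera adjusted p = 0.829). Where the changed part of the gene lies relative to the 23 probes is not given in the sources used here, so the Pcyt2 value does not check the genotype. Without male replicate 3 the difference was -0.02, and without male replicate 1 it was 0.18.

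Genes of the sex chromosomes gave the clearest differences and checked the labels. Xist, the noncoding RNA that coats and silences 1 X chromosome in female cells (X, 103460373 to 103483233), was at 10.02 ± 0.08 (SD, n = 4) in females and 4.33 ± 0.81 (SD, n = 4) in males, 51.5-fold higher in females (adjusted p = 4.60e-05). Its 3 probe sets gave log2 differences between -6.31 and -5.02. The size of the fold depends on the low male signal. With each array left out in turn the difference lay between -6.09 and -5.51. The Y-linked RNA helicase Ddx3y (Y, 1260715 to 1286613) and translation initiation factor subunit Eif2s3y (Y, 1010543 to 1028594) were 17.6- and 24.3-fold higher in males. The histone demethylase Kdm5d (Y, 897788 to 943811) and Uty (Y, 1096861 to 1245759) were 12.8- and 19.4-fold higher in males. Females have no Y chromosome, so their values are background signal and the size of these folds depends on it. The adjusted p of these 4 genes lay between 3.44e-08 and 1.61e-05, and the 4 male values of each lay above the 4 female ones. No array stood with the other sex. Of 7 measured genes on the Y-linked list, 4 passed over all genes and the same number when adjusted over the list alone (camera adjusted p = 1.22e-17, and 0.00526 with an estimated correlation).

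Genes that escape X inactivation were higher in females. The histone demethylase Kdm6a (X, 18162575 to 18279936) was at 7.67 ± 0.13 (SD, n = 4) in females and 6.88 ± 0.09 (SD, n = 4) in males, a log2 difference of -0.78 with a standard error of 0.09 (adjusted p = 0.0271). Of 13 measured genes on the list of X inactivation and escape genes, 2 passed over all genes, Xist and Kdm6a, and 7 when adjusted over the list alone, all of them higher in females. Among these were the histone demethylase Kdm5c (log2 difference -0.62) and the RNA helicase Ddx3x (-0.45), whose 4 female values lay above the 4 male ones but whose adjusted p over all genes were 0.166 and 0.248. With a trend in eBayes both passed over all genes (0.0177 and 0.0119), as they did with the robust form (0.0140 and 0.00993). The remaining 3, named after their values were seen, were Pbdc1 (-0.43) and the noncoding RNAs Ftx (-0.40) and Jpx (-0.29). The list passed as a group (camera adjusted p = 1.30e-13, and 0.00526 with an estimated correlation). Kdm6a lost its call when any 1 of the 8 arrays was left out, with an adjusted p between 0.0507 without female replicate 3 and 0.167 without male replicate 3, and a difference between -0.83 and -0.72. Over 8 other alternatives its adjusted p ran from 0.000748 to 0.225, under 0.05 in 6.

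Outside the sex chromosomes little passed a test gene by gene. Across all 28273 genes, limma with Benjamini-Hochberg adjustment called 7, of which 5 were higher in males and 2 in females; 4 are Y-linked, 2 X-linked and 1 autosomal. The autosomal gene is Ano5, which encodes an anoctamin membrane protein of muscle (chromosome 7, 51511029 to 51598709). It was at 4.04 ± 0.09 (SD, n = 4) in males and 3.29 ± 0.12 (SD, n = 4) in females, a log2 difference of 0.75 with a standard error of 0.09, or 1.68-fold (adjusted p = 0.0282). Its signal was low, with 35.9% of genes dimmer in females and 51.8% in males. The female mean was close to the background of 3.22 that Ddx3y gave in females. With p adjusted over autosomal genes alone, as the plan for autosomes set, the count was 0 and the adjusted p of Ano5 was 0.188. At an unadjusted p under 0.05, 1536 autosomal genes stood out, 759 higher in males and 777 in females, which is 5.69% of those tested where chance gives 5%. Ano5 kept an adjusted p under 0.05 over all genes when female replicate 1 was left out (0.0373). It lost it, at 0.0657 without male replicate 4 to 0.167 without male replicate 3, when any 1 of the other 7 arrays was left out, and over 8 other alternatives ran from 0.0259 to 0.470.

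The autosomal genes next in line had non-overlapping male and female values but did not pass. Among those higher in males, skeletal alpha-actin Acta1 (chromosome 8, 123891767 to 123894751) was at 9.84 ± 0.36 (SD, n = 4) in males and 8.67 ± 0.22 (SD, n = 4) in females, 2.25-fold apart (adjusted p = 0.166). The terminal complement component C7 differed by 1.60 (standard error 0.28, adjusted p = 0.280), the phosphodiesterase Pde11a by 0.71 and the complement protease gene C1rb by 0.58. On the female side, the monocarboxylate transporter Slc16a7 had a log2 difference of -0.63 (standard error 0.10, adjusted p = 0.248), Lrrc55 of -0.59, the small nucleolar RNA gene Rnu3a of -0.60 and Apol7b of -0.65. Sdr16c6, the other gene in this group, was near the floor of the arrays, with 1.7% of genes dimmer in males, so no difference is given for it. Y-linked genes gave a background in females from 2.22 (Kdm5d) to 3.22 (Ddx3y). The male means of Rnu3a (3.24) and Apol7b (2.75) and the female mean of C1rb (3.03) lay near it. The size of these 3 differences depends on that background. The dimmer probe set of Lrrc55 gave -0.07, so its value rests on 1 of 2 probe sets. Male and female values did not overlap for 984 genes, 3.48% of those tested, where chance gives 2.86%.

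**Figure D1:**
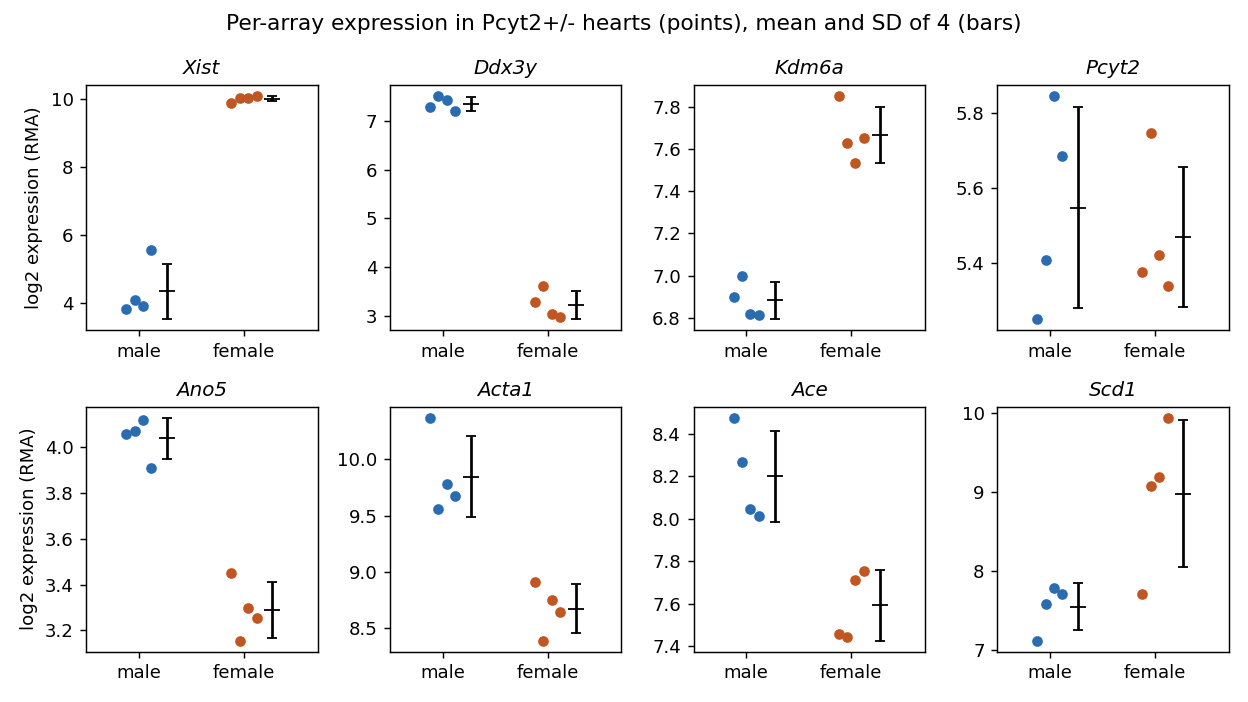
Log2 expression (RMA) of 8 genes in each array, males in blue and females in orange, with the mean and SD of 4 arrays as black bars; each panel has its own vertical scale, which does not start at 0. Xist, Ddx3y, Kdm6a and Ano5 separate the sexes and passed the test over all genes, while the Pcyt2 values of males and females overlap.

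Genes were also compared as groups. Of 33 lists fixed before the data were examined, 7 passed a camera test with a preset correlation of 0.01, 3 higher in males and 4 higher in females. With the correlation estimated for each list, 3 passed: the Y-linked list, the X inactivation list and the interferon list. In the same arrays the adipocyte marker list, which marks another cell type, was higher in females with a median log2 difference of -0.40.

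Extracellular matrix genes were higher in males as a group. Of 29 measured members, 27 had a positive difference, with a median of 0.20 (camera adjusted p = 3.32e-11). The call was lost with the correlation estimated for this list, 0.301 (adjusted p = 0.232, the largest over 21 alternatives), and with fry (0.168). The 19 alternatives that kept the call all used the preset correlation of 0.01, so they do not test that setting. No member passed over all genes, 0 passed when adjusted over the list alone, and 10 had an unadjusted p under 0.05, all higher in males. The members with the smallest p were the collagen crosslinking enzyme Lox (log2 difference 0.64, standard error 0.16), the microfibril protein fibrillin-1, Fbn1 (0.43, 0.11), the basement membrane collagen Col4a2 (0.37, 0.10) and the short-chain collagen Col8a1 (0.52, 0.18). Fibroblast markers had a median difference between the sexes of 0.01, with 6 of 12 on each side (camera adjusted p = 0.829). Within each sex the array at one end was the same on both lists: male replicate 1 had the highest fibroblast mean of the males (0.11) and female replicate 1 the lowest of the females (-0.20). The list means per array were 0.31, 0.15, -0.08 and 0.11 in males and between -0.23 and -0.03 in females, so male replicate 3 fell among the females. The exact permutation test of these means gave p = 0.0857.

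Hypertrophy and fetal-program genes, which the heart raises under load, were also higher in males as a group. Of 18 measured members, 15 had a positive difference, with a median of 0.20 (camera adjusted p = 2.58e-07). The call was lost with an estimated correlation (adjusted p = 0.232), and 19 of 21 alternatives kept it. None passed over all genes, 9 had an unadjusted limma p under 0.05, all higher in males, and 4 passed when adjusted over the list alone. These were Acta1 (log2 difference 1.17), the matrix protein gene Cilp (0.88), the acute-phase serpin Serpina3n (0.58) and Ddah1 (0.34), which degrades methylated arginines. Male replicate 3 had a list mean of -0.12, inside the female range of -0.19 to -0.03. The exact permutation test of the list means gave p = 0.0857. The atrial natriuretic peptide gene Nppa, which is also an atrial marker, differed by -0.03, and list means of atrial markers ran from -0.66 to 0.51 over the 8 arrays.

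Interferon-response genes were higher in females. Of 22 measured members, 21 had a negative difference, with a median of -0.23 (camera adjusted p = 4.97e-09, and 0.0376 with an estimated correlation). None passed over all genes, 9 had an unadjusted limma p under 0.05 and 5 passed when adjusted over the list alone. They were the immunoproteasome subunit gene Psmb9 (log2 difference -0.36), the ISG15 protease gene Usp18 (-0.34), Ifit1 (-0.32) and Ifi44 (-0.28), which are induced by type I interferon, and the guanylate-binding protein gene Gbp3 (-0.33), named after its value was seen. Each of the 4 female list means (0.05 to 0.21) lay above the 4 male ones (-0.14 to -0.04), with an exact permutation p of 0.0286, the smallest this design allows. List means of T and B lymphocyte markers separated the sexes too, at -0.02 to 0.12 in females and -0.10 to -0.03 in males (exact permutation p = 0.0286), though that list did not pass (camera adjusted p = 0.111). Female replicate 1 was the highest array for interferon genes, and without it the list kept an adjusted p of 1.25e-06.

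Genes of the unfolded protein and integrated stress response were higher in females as a group, by less. Of 19 measured members, 15 had a negative difference, with a median of -0.11 (camera adjusted p = 0.00225). The call was lost with an estimated correlation (adjusted p = 0.208), with fry (0.151), without male replicate 4 (0.0598) and with the adipocyte list mean as a covariate (0.0876). Over 21 alternatives, of which 17 kept the call, the adjusted p ran from 0.000138 to 0.208. None passed over all genes and 0 when adjusted over the list alone, while 3 had an unadjusted limma p under 0.05. The members with the smallest p were chaperones and other proteins of the endoplasmic reticulum: Sdf2l1 (log2 difference -0.42), Hsp90b1 (-0.23), Calr (-0.19) and Pdia6 (-0.19). Heat shock proteins, a separate list, did not pass (13 measured, median -0.04, adjusted p = 0.829).

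Adipocyte markers were higher in females. Of 14 measured members, 13 had a negative difference, with a median of -0.40 (camera adjusted p = 3.09e-06). The call was lost with an estimated correlation (adjusted p = 0.422), and 19 of 22 alternatives kept it. No member passed over all genes and 0 passed when adjusted over the list alone, while 7 higher in females and 1 higher in males had an unadjusted limma p under 0.05. Carbonic anhydrase Car3 was at 8.51 ± 0.98 (SD, n = 4) in females and 7.20 ± 0.72 (SD, n = 4) in males, a log2 difference of -1.31. The adipokine gene Retn differed by -0.72, the acute-phase protein gene Orm1 by -0.48 and the beta-3 adrenoceptor gene Adrb3 by -0.31. Female replicate 4 had the highest list mean at 0.63, and male replicate 3, at 0.10, lay above female replicates 1 and 3. The exact permutation test of the list means gave p = 0.0857.

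The list of fatty acid and sterol synthesis did not pass, and neither did any of its enzymes. Stearoyl-CoA desaturase Scd1 was at 8.97 ± 0.93 (SD, n = 4) in females and 7.54 ± 0.30 (SD, n = 4) in males, a log2 difference of -1.43 (adjusted p = 0.681). Fatty acid synthase Fasn differed by -0.83, the elongase Elovl6 by -0.53 and acetyl-CoA carboxylase Acaca by -0.42. Over all 22 measured genes of fatty acid and sterol synthesis the median was -0.03 (camera adjusted p = 0.152), with 0 past the threshold over all genes or adjusted over the list alone. The list passed without female replicate 1 (0.00123) and in no other of 21 alternatives, over which the adjusted p ran up to 0.953. Genes of fatty acid uptake and oxidation did not pass either, with 26 of 33 positive and a median of 0.07 (camera adjusted p = 0.0623). Its members with the smallest p were the lipoprotein lipase inhibitor Angptl4 (0.61) and the coactivator Ppargc1a (-0.20). That list passed without male replicate 1 (0.0279), without male replicate 2 (0.00564) and without female replicate 2 (0.00514), and in 8 of 21 alternatives in all, with adjusted p from 0.000777 to 0.763. Triglyceride synthesis, storage and lipolysis did not pass (25 measured, median 0.02, adjusted p = 0.221), with the lipid droplet proteins Plin5 at 0.29 and Plin2 at 0.17. It passed, higher in males, in 1 of 21 alternatives, with the adipocyte list mean as a covariate (0.00918, with up to 0.763 over the others).

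**Figure D2:**
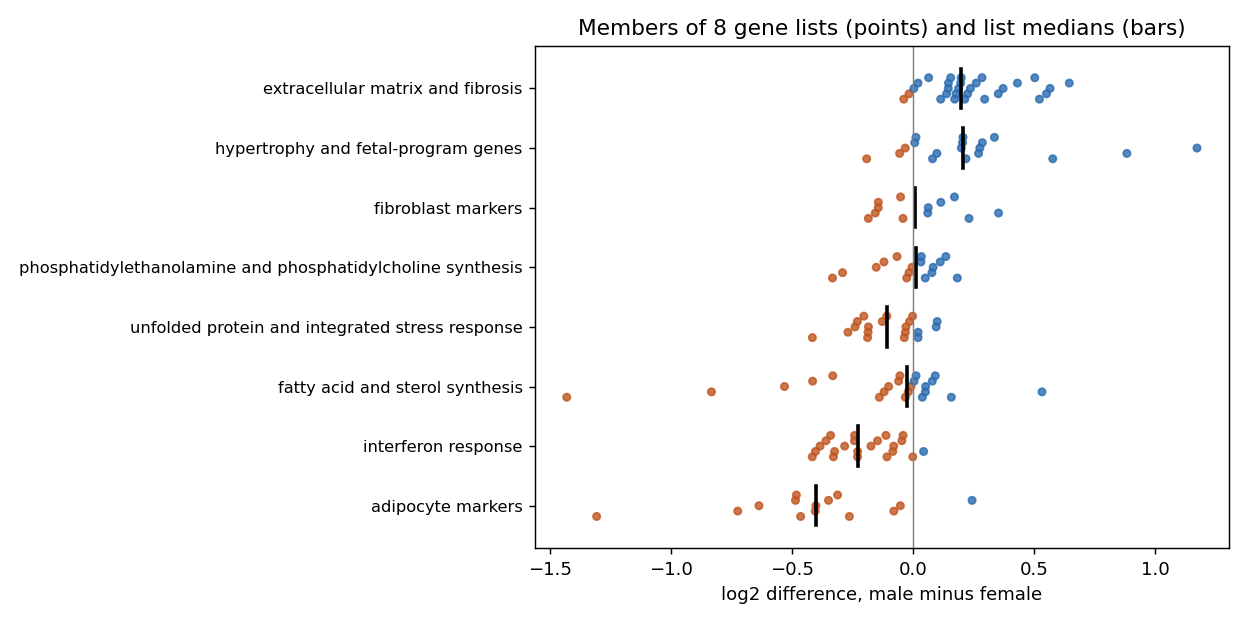
Log2 difference, male minus female, of each measured member of 8 gene lists (points, blue above 0 and orange below 0) with the list median as a black bar. Extracellular matrix and hypertrophy genes lie mostly above 0, with medians of 0.20 each, and interferon and adipocyte genes mostly below 0, with medians of -0.23 and -0.40. Fibroblast markers centre on 0.01.

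Apart from adipocyte markers, no list of cell type markers passed, which does not show that they were level. Atrial myocyte markers had a median difference of -0.15 (13 measured, camera adjusted p = 0.221), but their list means ran from -0.66 to 0.51 over the 8 arrays, with male replicates 1 and 3 and female replicate 1 low. That list passed, higher in females, without female replicate 1 (9.62e-05) and without male replicate 2 (0.0403), and in 3 of 21 alternatives in all, with adjusted p up to 0.974. Endothelial markers had a median of 0.00 (13 measured, adjusted p = 0.437), and the receptor gene Kdr differed by 0.20. They passed, higher in males, with the adipocyte list mean as a covariate (0.0266), with up to 0.863 over 21 alternatives. Smooth muscle and pericyte markers had a median of 0.06 (12 measured, adjusted p = 0.156) and passed without male replicate 2 (0.0421), with up to 0.423 over 21 alternatives. Their smooth muscle myosin Myh11 differed by 0.24. Macrophage markers did not pass (17 measured, median -0.04, adjusted p = 0.459), nor did neutrophil markers (11 measured, median -0.04, adjusted p = 0.459), where myeloperoxidase Mpo differed by -0.35. T and B lymphocyte markers had a median of -0.13 (15 measured, adjusted p = 0.111) and passed without female replicate 2 (0.0448), with up to 0.799 over 21 alternatives. The T cell receptor complex gene Cd3g differed by -0.48. Erythroid markers, with 3 of 10 measured, had a median of -0.16 (adjusted p = 0.661). Mesothelial, lung, nerve and thymus markers had a median of -0.03 (15 measured, adjusted p = 0.829).

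**Figure D3:**
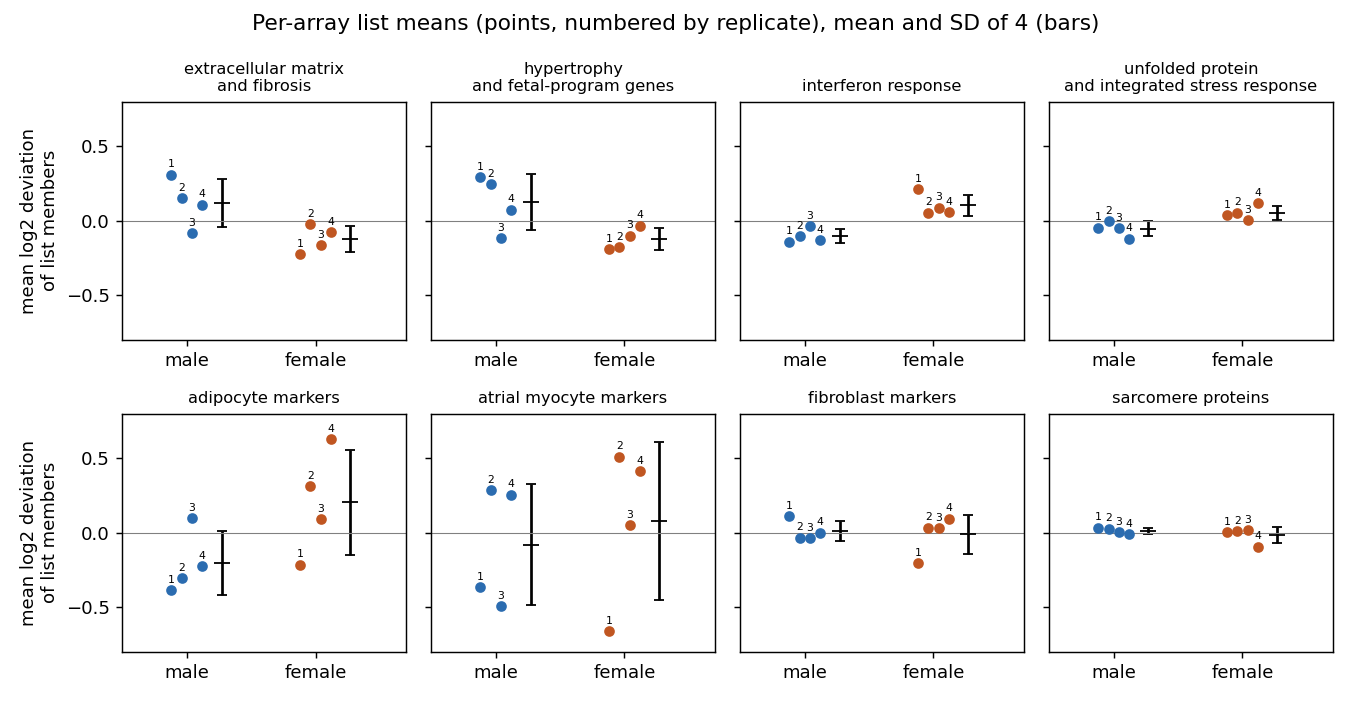
Mean log2 deviation of the members of 8 lists in each array, numbered by replicate, males in blue and females in orange, with the mean and SD of 4 arrays as black bars, on a shared vertical axis. Interferon-response and unfolded protein response means separate the sexes, extracellular matrix and hypertrophy means overlap through male replicate 3, and atrial markers span -0.66 to 0.51 while sarcomere proteins span -0.09 to 0.04.

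Genes of contraction and energy metabolism did not differ as groups. Oxidative phosphorylation had a median difference of 0.00 over 39 measured genes (camera adjusted p = 0.777) and glucose transport, glycolysis and glycogen of 0.02 over 24 (0.459). Sarcomere proteins had a median of 0.03 over 21 genes and calcium handling of 0.02 over 17, both with an adjusted p of 0.459. In each of these 4 lists 0 members passed over all genes or adjusted over the list alone. The calsequestrin gene Casq2 differed by 0.16 and the M-band protein gene Myom2 by -0.17.

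Single members stood out on lists of ion channels and blood pressure signalling whose other members went both ways. The sodium channel subunit gene Scn4b was at 6.41 ± 0.36 (SD, n = 4) in males and 5.69 ± 0.25 (SD, n = 4) in females, a log2 difference of 0.72, and the potassium channel gene Kcna5 differed by -0.24. Angiotensin-converting enzyme Ace was at 8.20 ± 0.21 (SD, n = 4) in males and 7.59 ± 0.16 (SD, n = 4) in females, a difference of 0.61, and Corin, the protease that activates atrial natriuretic peptide, differed by -0.34. On the list of sex steroid receptors and metabolism, the estrogen receptor gene Esr1 differed by -0.19. None of these passed over all genes, with adjusted p between 0.516 and 0.858. Adjusted over the list alone, Ace and Corin passed and 0 of 23 ion channel genes did. Camera, which asks whether a list moves one way, did not call the ion channel list (adjusted p = 0.459), the blood pressure list (24 measured, 0.753) or the sex steroid list (14 measured, 0.498). Fry's mixed test, which asks whether members differ in either direction, gave adjusted p of 0.00264, 0.00281 and 0.000461 for the same lists. Of the 33 lists, 8 had an adjusted p under 0.05 in the mixed test, so passing it was not particular to these lists.

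The remaining lists did not pass. Circadian clock genes had a median of -0.08 (18 measured, camera adjusted p = 0.221), with the clock activator gene Arntl at 0.36, Rora at -0.21, Per3 at -0.20 and Tef at -0.20 (0.07 on its dimmer probe set). Glucocorticoid targets had a median of -0.08 (15 measured, adjusted p = 0.181), with Klf9 at -0.21, and passed without male replicate 2 (0.0403), female replicate 1 (0.0193) or female replicate 2 (0.00620), with up to 0.909 over 21 alternatives. Immediate early genes had a median of 0.07 (17 measured, adjusted p = 0.152), with Ccn1 at 0.30, and passed without female replicate 4 (0.0301), with up to 0.763 over 21 alternatives. Autophagy genes had a median of -0.03 (21 measured, adjusted p = 0.459) and antioxidant defence genes of -0.02 (23 measured, adjusted p = 0.753). No gene on these 5 lists passed over all genes or adjusted over the list alone.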

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

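The tests of an uneven share of atrial tissue, of weak arrays, of fibroblasts and of adipose tissue were chosen only after the results they address were seen, as were the covariates. Values of 4 arrays of a sex were marked when the gap between the array at one end and its nearest neighbour, over the range of the 4, exceeded 0.829. Of 344 sets of 4 values 16 did, where chance marks about 1 in 20 (5%).

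In males, Xist was at 5.54 in replicate 4 against 3.82 to 4.08 in the others (0.847). Angptl4 was at 4.64 in male replicate 1 against 4.03 to 4.05 (0.959). The club cell secretoglobin Scgb1a1, a lung marker, was at 3.40 in male replicate 1 against 2.40 to 2.47 (0.928). The mean of the Y-linked list was lowest in male replicate 3, at 1.16 against 1.21 in the others (0.865). The calcium handling mean was highest in male replicate 4 (0.07, ratio 0.886) and the endothelial mean in male replicate 3 (0.06, ratio 0.890).

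In females, replicate 1 stood apart for Ifit1 (6.01 against 5.74 to 5.76, ratio 0.937), Cd3g (4.29 against 3.88 to 3.93, 0.872), Myh11 (5.74 against 5.85 to 5.87, 0.834) and the glutathione synthesis gene Gclm (7.61 against 7.26 to 7.31, 0.833). Female replicate 2 stood apart for Mpo (3.54 against 3.16 to 3.22, 0.857), Kdr (8.36 against 8.07 to 8.11, 0.851), the immediate early gene Nr4a1 (5.57 against 6.13 to 6.24, 0.835) and Kdm5d (2.08 against 2.26 to 2.29, 0.835). The sarcomere mean was lowest in female replicate 4 (-0.09, ratio 0.877) and the neutrophil mean highest in female replicate 3 (0.14, ratio 0.894).

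Atrial marker transcripts differed between arrays of the same sex. The atrial growth factor Bmp10 was at 4.20, 8.78, 5.87 and 8.92 in males and at 4.00, 9.31, 7.96 and 8.89 in females. The list mean of sarcomere transcripts spanned 0.109 of the range of the atrial one. The arrays were normalized to each other and the atrial markers spread widely, so this ratio could not detect weak or degraded arrays. Weak or degraded arrays stay open. An uneven share of atrial tissue in the pieces stays a candidate explanation: the other atrial markers followed the atrial myosin light chain Myl7 within each sex with a median correlation of 0.884, positive for 12 of 12, and their mean correlated with Myl7 at 0.976 (exact permutation p = 0.00174 over 576 pairings, adjusted p = 0.00347 over 2 relations; Spearman 0.976, p = 0.00347; 0.940 without female replicate 1 and male replicate 3). Biological variation between the mice was not tested.

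Extracellular matrix and hypertrophy genes were higher in males. Whether an uneven atrial share was the cause could not be decided. With the atrial list mean as a covariate both lists kept their camera call (adjusted p = 6.92e-13 and 4.49e-08). That test used the preset correlation. Without the covariate, both lists lost their camera call with an estimated correlation (adjusted p = 0.232 for each). Keeping the call at the preset correlation is therefore no evidence against an atrial share. More fibroblasts in the male pieces could not be excluded: the sex difference of the matrix list exceeded that of the fibroblast list by 0.223, with an exact permutation p of 0.0571. Chance could not be excluded either, as 3 of the 35 ways to split the arrays into 4 and 4 gave as small a camera p for the matrix list (real 3.02e-12, smallest other 3.73e-19) and 2 for the hypertrophy list (3.90e-08 and 3.68e-09). A difference between the sexes stays open.

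Adipocyte markers were higher in females as a list, and the lipogenic enzymes Scd1, Fasn, Acaca and Elovl6 had differences of -1.43, -0.83, -0.42 and -0.53, none of which passed over all genes or over their list alone. Adipose tissue left on the hearts to different extents stays a candidate explanation, since the other adipocyte markers followed the adipokine Adipoq within each sex with a median correlation of 0.658, positive for 13 of 13, and their mean correlated with it at 0.824 (exact permutation p = 0.0313 over 576 pairings; Spearman 0.857, p = 0.0191; 0.809 without male replicate 1 and female replicate 4). With the adipocyte list mean as a covariate the median difference of Scd1, Fasn, Acaca and Elovl6 went from -0.68 to -0.337, which left 49.4%, close to the bound set for this explanation. These 4 had the smallest p of the 22 measured genes of their list, whose median was -0.03. A median of genes picked this way can shrink with a covariate, so the test cannot decide. Adipose tissue may account for part of the difference. Chance could not be excluded for the adipocyte list, as 5 of 35 splits gave as small a p (real 5.62e-07, smallest other 2.54e-15). A difference between the sexes in the myocardium stays open and was not tested.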

How the results depend on the processing

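All alternatives were planned except the covariates and the shortened adipocyte list, chosen after seeing the data. None of the results turned direction and passed; of 2674 values of genes and lists that had not passed, 35 turned sign. Of 2224 values for named genes 2199 kept their side of the threshold, 19 lost a call and 6 gained 1. Lists that had not passed stayed so in 526 of 546 values.

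The count of 7 genes went to 11 with a trend in eBayes, robust or not, and to 391 (357 autosomal) at an unadjusted p under 0.05 and at least 1.3-fold; the looser threshold accounts for the last, and for the trend the cause was not tested. The autosomal count was 0 in all other alternatives. With a trend Acta1 gained a call over all genes (0.0177), though not over autosomes alone. The count of 7 lists went to 3 with an estimated correlation and to 3 with fry. With an estimated correlation the lists lost were hypertrophy (adjusted p = 0.232), extracellular matrix (0.232), unfolded protein response (0.208) and adipocyte markers (0.422). With fry they had 0.151, 0.168, 0.151 and 0.423; the cause was not tested. With the adipocyte covariate the unfolded protein response had 0.0876 (cause not tested) and the adipocyte list 0.951, which follows from its own mean being the covariate. With it, triglyceride synthesis (0.00918), fatty acid oxidation (0.000777) and endothelial markers (0.0266) gained a call, all higher in males, and Ano5 (0.470) and Kdm6a (0.151) lost theirs.

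With each array left out in turn, the ranges were 5 to 6 genes, 0 autosomal genes, 6 (without male replicate 4) to 11 lists (without male replicate 2), and -0.02 to 0.18 for Pcyt2. The lists were tested there at the preset correlation of 0.01. Adjusted p ranged from 3.46e-10 to 0.000570 for adipocyte markers, 1.25e-16 to 4.50e-07 for extracellular matrix, 4.41e-10 to 0.000106 for hypertrophy, 1.99e-09 to 1.25e-06 for interferon, 0.000933 to 0.0598 for the unfolded protein response, 3.28e-14 to 3.95e-11 for X inactivation and 9.60e-18 to 3.28e-14 for Y-linked genes.

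Deviations of same-numbered male and female arrays correlated weakly (0.03, 0.06, 0.03 and -0.002 for numbers 1 to 4). Even so, for numbers 2 and 3 the same-numbered array of the other sex was the best match in both directions. For number 1 this held in a single direction and for number 4 in neither. A batch that follows the replicate number is therefore not excluded. As a block the replicate numbers gave 6 genes, 5 of them shared, and 8 lists. The atrial list (0.0234, higher in females) and Acta1 (0.0425) gained a call and Kdm6a (0.225) and Ano5 (0.239) lost theirs. The workbook's values were not run, and a log2 offset did not apply. A smaller and a larger filter on dim genes gave 8 and 6 calls. Ano5 was not among the 6.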

Other observations

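The groups of RNA genes and annotation terms were chosen for testing only after the data were seen, while the splits were planned. Small nucleolar and Cajal body RNA genes, which guide the chemical modification of ribosomal and spliceosomal RNA, were higher in females as a group. Over 81 genes the median difference was -0.18 (camera adjusted p = 1.39e-08 over 4 groups, 0.0980 with an estimated correlation), with 14 higher in females and 2 in males at an unadjusted limma p under 0.05. The array means were -0.13, -0.15, -0.01 and -0.04 in males and 0.07, 0.21, 0.07 and -0.02 in females (exact permutation p = 0.0571). Ribosomal protein genes had a median of -0.05 over 64 genes (adjusted p = 0.0145, 0.355 with an estimated correlation). MicroRNA genes (504, median -0.01, adjusted p = 0.642) and mitochondrially encoded genes (28, median 0.00, adjusted p = 0.747) did not pass.

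Of 1254 annotation terms, camera called 1 higher in males and 0 higher in females. The term was the structural constituents of extracellular matrix (26 genes, median 0.10, adjusted p = 0.00296, 0.994 with an estimated correlation). At an unadjusted camera p under 0.05 there were 36 terms higher in males and 23 in females, where chance gives 5% of the terms tested. The first principal component over 14136 genes, with 22.8% of the variance, separated the sexes, from -13.51 to -5.79 in males and from 5.10 to 12.27 in females. Whether it would do so without X- and Y-linked genes is not shown. Among the 4447 probe sets with several symbols or none that the workbook annotates, limma called 0. At an unadjusted limma p under 0.05 there were 269, where chance gives 5% of those tested. The 6994 probe sets without workbook annotation were not tested.

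The arrays can be split into 4 and 4 in 35 ways, so a result reached by the real split alone has a share of 2.86%. No other split called a gene, against 7 in the real one. Of the 7, 4 are Y-linked and 2 X-linked, and every other split mixes the sexes. That count was thus largely fixed beforehand by the sex chromosomes and does not test chance. For autosomal genes all 35 splits gave the same 0. Chance cannot be excluded for the number of lists, since 9 of 35 splits gave at least 7 and the highest other gave 8. The outcome was fixed beforehand by sex for the Y-linked list (1 of 35, camera p 3.71e-19, smallest other 0.000248). The same holds for the X inactivation list (1 of 35, 7.86e-15, 8.20e-05). The interferon list was also reached by the real split alone (1 of 35, 6.03e-10, 1.99e-06). That is the smallest share this design allows, and with 33 lists tested about 1 would meet it by chance. Chance is therefore not excluded over all lists. For the small nucleolar RNA genes 1 of 35 splits gave as small a p (3.47e-09, smallest other 6.50e-09), but the group was chosen after the data were seen and its array means gave an exact permutation p of 0.0571, so chance stays open. It is not excluded for the unfolded protein response (2 of 35; 0.000477, 0.000287) or the matrix term (2 of 35; 2.36e-06, 1.01e-11).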
